A study of Homo sapiens with 6 samples.

How the data were processed

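RNA sequencing values of 6 libraries of LNCaP prostate cancer cells were used, 3 transfected with siRNA against GRHL2 and 3 with a control siRNA. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a directional (strand-preserving) kit. Per the submitters' processing notes, TopHat2 version 2.0.9, HTSeq, DESeq2 and R version 3.0.1 were used with the genome build hg19. The role of each tool is not given in the sources used here, nor is the strand setting of the counting. The deposited file holds rlog values, a log2 scale on which the authors' normalization also draws each gene's values toward its mean. This shrinks fold changes, more so for genes with few reads, and a gene seen in 1 library only appears in the others at a shared value that is not its level there. The rlog values run from -2.39 to 17.81. Raw counts and library sizes were not used here, so depth is unknown and no interval that needs it is given. Differences between libraries in depth cannot be seen in these values.

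Columns were assigned to libraries by the sample titles, which name the siRNA and the replicate, and 0 columns of per-sample values were left unused. Of the 19391 gene symbols, 16481 matched a current symbol. Symbols are given as in the file, so some are older ones (BAI2, HIST1H2BJ). Genes with a mean rlog of at least 3 over the 6 libraries were tested, which left out 4303 genes.

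The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a mean-variance trend, two-sided, no covariate, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). Standard errors come from the moderated variances, and confidence intervals are at 95%. Gene lists were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the 25 lists tested. Of the 26 lists fixed, the mitochondrially encoded genes had 0 genes in the file and were not tested. Lists need at least 5 genes. camera called 8 lists, and 0 of them with the correlation estimated per list. For epithelial junctions the estimate was -0.0133, under the preset value, so a higher correlation is not why that list lost its call. The setting thus changes more of the test than the correlation. fry, a rotation test of whether a list's genes move on balance one way, called 10: 7 of those 8 (S phase was at 0.053) and the luminal, p53 and TGF-beta lists.

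The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names 24 genes of androgen signalling, epithelial and mesenchymal identity, the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold, without overlap and with a mean rlog of at least 5 where higher, and up to 3 called members of each list. Some genes that this rule names are not reported here. Further members of lists named as examples were chosen after their values were seen. The alternatives were no filter or a minimum of 5, a pseudocount of 8, median centring, quantile normalization, no trend, robust variances, the replicate number as a block, leaving out each library, and the other list tests. Alternatives added after seeing the data were leaving out 2 libraries with signals of other tissues, correcting for GC content and length, and leaving out genes with sequence word matches. The tissue marker lists for blood, retina and eye, brain, liver, skeletal muscle and pancreas were also added then, from genes whose values had not been looked at.

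Positions, transcript GC content, length and 3' untranslated regions came from GENCODE 29 (GRCh38), using the longest protein-coding transcript of each gene. These positions are not those of hg19. The GC and length correction was fitted per library with splines of 4 degrees of freedom over 12729 genes, 84.4% of those tested. At least 82% of each list had a value. Sequence words of 8 bases in 3' untranslated regions were scored by the mean fold change of genes with the word against those without, after removing trends with length and base composition, over 8942 genes with a mean rlog of at least 8 and at least 50 bases. Words in at least 100 genes were scored, and 100 shuffles of the fold changes gave the chance range.

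The scripts were tested on simulated data. For siGRHL2 against siNC over 15088 genes, 31% of 100 simulated changes of 0.3 on the log2 scale and 60% of 100 changes of 0.6 were recovered, with 4 false calls among 95. A list of 50 genes shifted by -0.15 gave a camera p of 1.13e-24, and 2 of 100 unshifted lists had a p under 0.05. The simulated genes were independent of each other. This rate therefore does not give the false calls for lists of correlated genes, such as S phase with an estimated correlation of 0.299. A word planted with a shift of -0.1 ranked 1 in the word scan of 8942 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the other steps.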

Results

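Gene expression was measured by RNA sequencing in LNCaP cells, an androgen-sensitive human prostate cancer cell line. The cells had been transfected with a small interfering RNA (siRNA) against GRHL2 or with a negative control siRNA, called siNC here. GRHL2 encodes grainyhead-like 2, a transcription factor of epithelial cells. There were 3 libraries in each group, from cells kept in serum-containing medium. The values were regularized log2 (rlog) values for 19391 genes, so the sequencing depth of each library is unknown. The library medians of the tested genes lay between 9.56 and 9.58. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Pairs of libraries correlated at r = 0.995 to 0.999 within groups and at 0.993 to 0.996 between groups, across genes.

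The comparison asked which genes depend on GRHL2 in these cells, with androgen-regulated genes as a main interest. GRHL2 itself was lower in all 3 siGRHL2 libraries, at 11.16 ± 0.04 (SD, n = 3) against 11.97 ± 0.02 (SD, n = 3) with siNC. The androgen-induced genes KLK3 and FKBP5 fell as well, but SLC45A3, also androgen-induced, rose and TMPRSS2 did not pass the test. Over all genes tested, 29.4% changed in one direction or the other. Of the genes tested in each list, 45 of 104 of the androgen response fell and 16 rose. For epithelial junctions 26 of 52 fell and 8 rose. For cholesterol synthesis 15 of 25 fell and 0 rose, and for fatty acid synthesis 11 of 17 fell and 2 rose. Ribosomal proteins had 24 of 55 higher and 0 lower, and histones 9 of 16 higher and 0 lower. S phase had 18 of 46 higher and 2 lower, and the unfolded protein response 18 of 34 higher and 5 lower. These lists passed the camera test, but none did with an estimated correlation (adjusted p = 0.337 to 0.685). For epithelial junctions that correlation was -0.0133, under the preset 0.01, so a higher correlation is not why its call was lost.

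The log2 fold change of GRHL2 was -0.81 (SE 0.0407, 95% confidence interval -0.90 to -0.72, limma adjusted p = 1.99e-05), the eleventh lowest of all genes tested. GRHL2 lies on chromosome 8 from 101492432 to 101669726 in GRCh38, on the plus strand. The rlog transformation draws values toward the mean of each gene. The largest range over the 6 libraries of any gene in the file was 1.23, and the fold changes given here are therefore smaller than those of read counts would be.

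**Figure D1:**
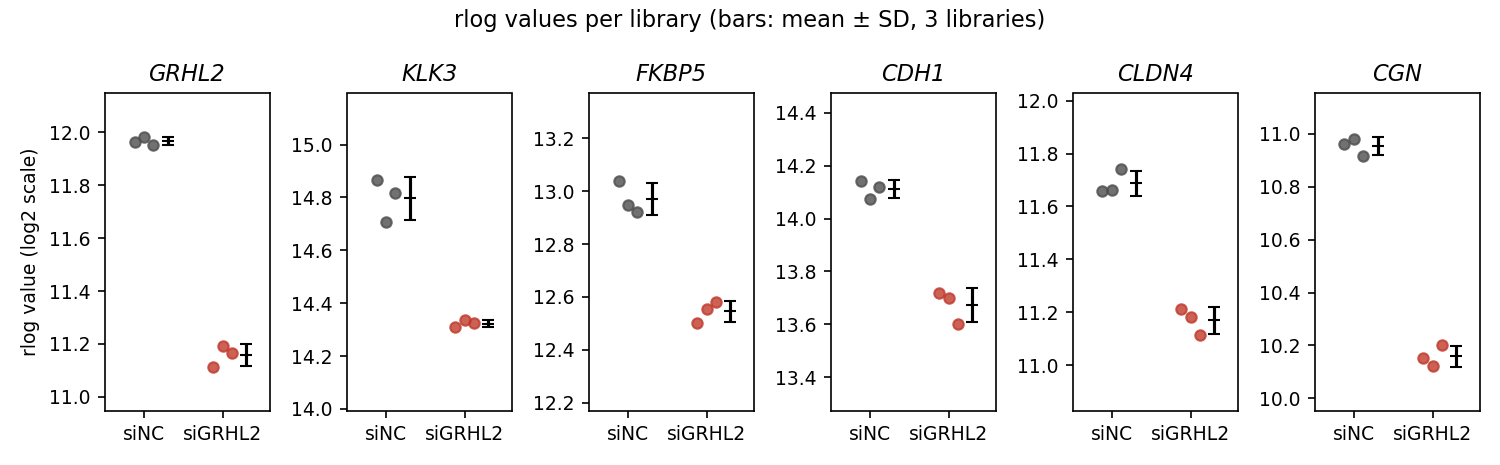
rlog values (log2 scale, y axis, each panel spanning the same number of units) of 6 genes in the siNC (grey) and siGRHL2 (red) libraries; points are libraries and the bars beside them give the mean ± SD of 3 libraries. In each of the 6 genes all siGRHL2 libraries lie below all siNC libraries, as for GRHL2 with means of 11.16 and 11.97.

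KLK3, which encodes prostate-specific antigen, changed by -0.47 (SE 0.0459, limma adjusted p = 0.000174) and FKBP5, an androgen-induced gene of the immunophilin family, by -0.42 (SE 0.0434, limma adjusted p = 0.000231). KLK2 changed by -0.31 (SE 0.0517), and this call was lost without the 2 libraries described further on (limma adjusted p = 0.0938). TMPRSS2 (-0.07, SE 0.0399), the pioneer factor gene FOXA1 (0.03, SE 0.0474) and HOXB13 (0.02, SE 0.038) did not pass the test. The telomerase gene TERT was at 0.10 (SE 0.0887, limma adjusted p = 0.446). Its values were 7.72 to 7.75 with siGRHL2 and 7.63 to 7.65 with siNC. The groups of TERT and TMPRSS2 thus did not overlap, while those of FOXA1 and HOXB13 did.

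Over all 15088 genes tested, 2230 were higher and 2207 lower after siGRHL2 at a limma adjusted p under 0.05, which is 29.4% of the genes. The fold changes ran from -0.85 to 0.82 on the log2 scale, and no gene reached a 2-fold change (0 higher and 0 lower by limma, with 6226 genes at an unadjusted p under 0.05). There were 387 genes higher by at least 0.5 and 410 lower by at least as much. The 3 libraries of one group did not overlap with the other 3 in 45.0% of the genes, against 10% by chance. The counts depended on single libraries of both groups. Leaving out siGRHL2 replicate 1, 2 or 3 gave 1252, 1252 and 1313 higher genes and 1273, 1391 and 1401 lower genes. Leaving out siNC replicate 1, 2 or 3 gave 1976, 1529 and 2584 higher and 1896, 1531 and 2786 lower genes.

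The genes with the largest increases were GCG (0.82), which encodes proglucagon, ADRA2A (0.81), the alpha-2A adrenergic receptor, TSPAN4 (0.81), the tubulin gene TUBB4A (0.80), LGI2 (0.80), the zinc finger gene ZBTB43 (0.79), MAP1A (0.78), SLC22A17 (0.78), the laminin gene LAMB1 (0.78) and BAI2 (0.78). The largest decreases were in SYT7 (-0.85), a synaptotagmin, RGL2 (-0.84), PSD4 (-0.84), the syndecan gene SDC4 (-0.84), STAP2 (-0.83), WWC3 (-0.82), PROM2 (-0.82), CARD14 (-0.82), the transcription factor gene TFAP2C (-0.81) and the protein kinase C gene PRKCH (-0.81). The standard errors of these 20 genes lay between 0.0399 and 0.0915, and none of them overlapped between the groups.

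Of 104 measured genes of the androgen response list, 45 fell, 16 rose and 43 did not pass the test (50 lower and 21 higher when adjusted over the list alone). Besides KLK3 and FKBP5, the aldehyde dehydrogenase gene ALDH1A3 (-0.75), the cation channel gene TRPM8 (-0.75) and the kinase gene AKT1 (-0.69) fell. SLC45A3 (0.63), PMEPA1 (0.42) and KLK4 (0.27), also androgen-induced genes, rose. The list as a whole was lower (camera adjusted p = 0.0007, median -0.13), with adjusted p = 0.378 with an estimated correlation, and 24 of its genes are also in other lists. Without the genes whose 3' untranslated region holds at least 7 of the 8 bases of the sequence words that went with lower values after siGRHL2, a pattern found in these same values and taken up among the other observations, its camera adjusted p was 0.263, with a median of -0.05 over the 52 genes left. Of 18 measured androgen-repressed genes, 7 rose and 5 fell (camera adjusted p = 0.470), with DDC at 0.67, ST7 at 0.63 and SYT4 at -0.70. Of 18 luminal prostate genes, 4 rose and 7 fell (adjusted p = 0.454). Of 28 prostate transcription factors and cofactors, 5 rose and 5 fell (adjusted p = 0.456), and the coactivator gene NCOA3 fell by 0.42. Of 15 basal prostate genes, 1 rose and 1 fell (adjusted p = 0.993). Adjusted over the list alone, the counts of these 4 lists did not differ.

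Of 52 measured genes of epithelial junctions and identity, 26 fell and 8 rose, while 18 did not pass (28 lower and 9 higher when adjusted over the list alone). The tight junction genes CGN (-0.79) and CLDN4 (-0.52), ARHGAP32 (-0.76), the epithelial transcription factor genes ELF3 (-0.70) and OVOL1 (-0.64) and the E-cadherin gene CDH1 (-0.44) fell. The plakophilin gene PKP2 (0.55), CLDN3 (0.48) and EPCAM (0.41) rose. GRHL1, a paralog of GRHL2, was lower (-0.41, SE 0.103), a call lost without siGRHL2 replicate 1 (limma adjusted p = 0.0708), siGRHL2 replicate 3 (0.0681) or siNC replicate 2 (0.0632). RAB25 (-0.15, SE 0.0565), ESRP1 (-0.01, SE 0.0692), OVOL2 (-0.06, SE 0.0889) and GRHL3 (0.36, SE 0.148) did not pass the test, although RAB25 passed it without siNC replicate 2 (0.044). The list was lower as a whole (camera adjusted p = 0.00212, median -0.16), with adjusted p = 0.337 with an estimated correlation. Without genes with a sequence word match, its camera adjusted p was 0.194, with a median of -0.12 over the 31 genes left.

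The mesenchymal list was not called (camera adjusted p = 0.126). Of its 51 measured genes, 9 rose and 4 fell, with the same counts when adjusted over the list alone. ACTA2 (0.63), the fibrillin gene FBN1 (0.54) and WNT5A (0.52) rose, and FN1 (-0.46), which encodes fibronectin, fell. ZEB1 (0.18, SE 0.206), ZEB2 (-0.03, SE 0.143), SNAI2 (0.22, SE 0.124), VIM (0.01, SE 0.188) and CDH2 (0.01, SE 0.130) did not pass. CDH2 stood at a shared value of 4.26 in every library but siGRHL2 replicate 1 (4.28), so its response could not be judged. VIM was highest in siGRHL2 replicate 1 (10.79) and siNC replicate 3 (10.57), against 10.07 to 10.16 in the others. ZEB1 and ZEB2 were likewise highest in these libraries, which are described further on. Of the 59 mesenchymal genes in the file, filtered ones included, 34 were highest in siGRHL2 replicate 1. The list passed without siGRHL2 replicate 2 (camera adjusted p = 0.0302) or replicate 3 (0.0333), and was at 0.597 without replicate 1.

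Of 25 measured genes of cholesterol synthesis, 15 fell and 0 rose, with the same counts when adjusted over the list alone. FDFT1, which encodes squalene synthase, changed by -0.56 (SE 0.0482), HMGCS1 by -0.53 (SE 0.0563) and INSIG1, a sterol-responsive gene, by -0.49 (SE 0.0385). The list was lower (camera adjusted p = 5e-05, median -0.18), with adjusted p = 0.378 with an estimated correlation. Of 17 genes of fatty acid synthesis, 11 fell and 2 rose (11 and 3 when adjusted over the list alone), among them the acyl-CoA synthetase gene ACSL1 (-0.63), the fatty acid synthase gene FASN (-0.48) and the desaturase gene SCD (-0.42). ACSL3 (0.35) and ME1 (0.20) rose. That list was also lower (camera adjusted p = 0.00166, median -0.21), with adjusted p = 0.378 with an estimated correlation and 0.242 without genes with a sequence word match (median -0.07 over the 7 genes left).

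**Figure D2:**
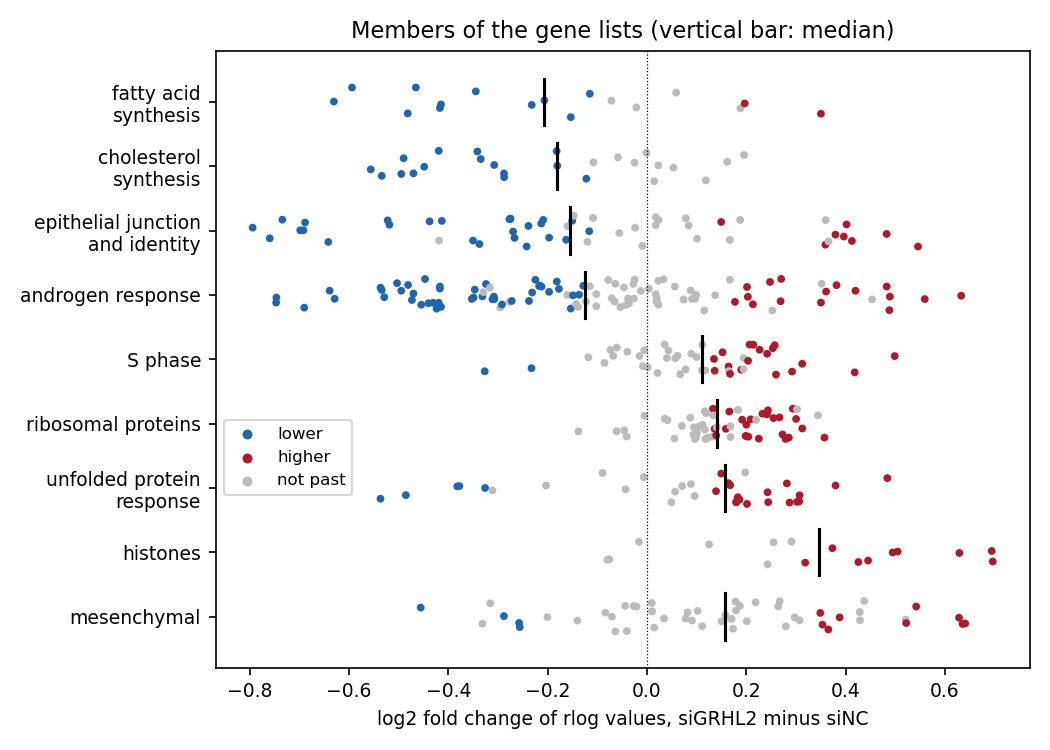
Log2 fold change of rlog values (siGRHL2 minus siNC, x axis) of each measured member of the 8 lists called by camera and of the mesenchymal list (rows); points are genes, coloured by whether they passed the limma test, and vertical bars are medians. The medians run from -0.21 for fatty acid synthesis to 0.35 for histones.

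Of 55 ribosomal protein genes, 24 rose and 0 fell (33 and 0 when adjusted over the list alone), by small amounts, as for RPL22 (0.36), RPLP2 (0.29) and RPL13A (0.29). The list was higher (camera adjusted p = 1.06e-07, median 0.14), with adjusted p = 0.378 with an estimated correlation. Many ribosomal protein genes have near-identical pseudogenes, so their values are uncertain where reads could be split between copies. Of 16 replication-dependent histone genes, 9 rose and 0 fell, over all genes and when adjusted over the list alone, with HIST1H2BJ at 0.70 and HIST1H2AG at 0.69 (camera adjusted p = 0.00077, median 0.35). The adjusted p was 0.378 with an estimated correlation, and these genes too have close copies. Of 46 genes of the S phase list, 18 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.00102, median 0.11). The thymidine kinase gene TK1 (0.50), FEN1 (0.29) and the replicative helicase gene MCM3 (0.24) rose, and the adjusted p was 0.685 with an estimated correlation. Of 49 genes of mitosis, 6 rose and 9 fell (7 and 9 when adjusted over the list alone, camera adjusted p = 0.937), with the proliferation marker MKI67 at 0.41 and the survivin gene BIRC5 at -0.54.

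Of 34 genes of the unfolded protein response, 18 rose and 5 fell (19 and 6 when adjusted over the list alone, camera adjusted p = 0.00971, median 0.16), with adjusted p = 0.378 with an estimated correlation. The chaperone genes CANX (0.31), PDIA3 (0.30) and HSPA5 (0.19) rose, but the co-chaperone gene DNAJB9 (-0.54) fell. SEL1L (-0.49), of the degradation machinery, and ERN1 (-0.38), a stress sensor, fell as well. In the remaining lists, 8 of 29 measured p53 targets rose and 3 fell (11 and 4 when adjusted over the list alone, camera adjusted p = 0.192), with DDB2 at 0.60 and MDM2 at -0.53. In the TGF-beta list 8 of 24 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.0890), with the inhibitor of differentiation genes ID1 at 0.71 and ID3 at 0.67. It passed without siGRHL2 replicate 2 (0.0444) or replicate 3 (0.0487). Of its genes in the file, 42.9% were highest in siGRHL2 replicate 1. Without the 2 libraries described further on, its camera adjusted p was 0.371 and its median 0.04, against 0.10 with all 6. Of 50 nuclear genes of oxidative phosphorylation, 11 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.200), and the list passed without genes with a sequence word match (0.0395). Of 34 hypoxia and glycolysis genes, 6 rose and 7 fell (the same adjusted over the list alone, adjusted p = 0.707). Of 12 polyamine genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.454).

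Several lists for other cell types or for stress moved with single libraries. Of 17 neuroendocrine genes tested, 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0890), and 70.8% of those in the file were highest in siGRHL2 replicate 1. This list passed without siGRHL2 replicate 2 (0.0302) or replicate 3 (0.0459). Of 14 fibroblast markers, 1 rose (1 adjusted over the list alone, camera adjusted p = 0.167), with 13 of the 18 in the file highest in siGRHL2 replicate 1, and the list passed without siGRHL2 replicate 2 (0.0444). Of 41 interferon response genes, 6 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.993), with 58.5% highest in siNC replicate 3. Of 25 immediate early genes, 2 rose and 1 fell (0 and 1 adjusted over the list alone, adjusted p = 0.595), with 18 of the 26 in the file highest in siNC replicate 3. Of 15 blood and endothelial markers, 0 rose and 0 fell by limma, and 12 were highest in siNC replicate 3 (camera adjusted p = 0.454). Of 23 NF-kappaB response genes, 4 rose and 1 fell (0 and 0 adjusted over the list alone, adjusted p = 0.470), and of those in the file 52.0% were highest in siGRHL2 replicate 1 and 40.0% in siNC replicate 3. This last list passed without siNC replicate 3 (0.0452).

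The same 2 libraries stood apart in markers of tissues other than prostate. Of 40 blood cell markers, 90.0% were highest in siNC replicate 3, and of 48 retina and eye markers, 87.5% were highest in siGRHL2 replicate 1. The hemoglobin gene HBB was at 10.24 in siNC replicate 3 against 9.97 to 9.98 in the others, and the glial gene GFAP at 10.93 in siGRHL2 replicate 1 against 10.56. Without these 2 libraries, 1582 genes were higher and 1804 lower by limma. Of the 4437 genes called with 6 libraries, 2789 were called again with these fewer libraries. All 4437 kept their direction (r = 0.99 between their fold changes in the 2 fits, which share libraries). This was nearly fixed in advance, since the groups did not overlap in 2227 of the 2230 higher and 2201 of the 2207 lower genes. For those, leaving out libraries cannot turn the direction. All 8 called lists passed again, among them androgen response and epithelial junctions (both camera adjusted p = 0.0121), but fewer of their members did. The counts went from 18 to 9 higher for the unfolded protein response, from 9 to 5 for histones, from 18 to 10 for S phase, and from 11 to 6 lower for fatty acid synthesis. Their medians went from 0.16 to 0.14, 0.35 to 0.41, 0.11 to 0.11 and -0.21 to -0.19 in the same order. The median of the mesenchymal list went from 0.16 to 0.005. Among other lists not called, p53 targets went from 8 to 4 higher, oxidative phosphorylation from 11 to 5 and polyamine genes from 3 to 0. Their medians went from 0.09 to 0.10, 0.05 to 0.07 and 0.10 to 0.11 in the same order. Interferon response went the other way, from 6 to 7 higher.

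**Figure D3:**
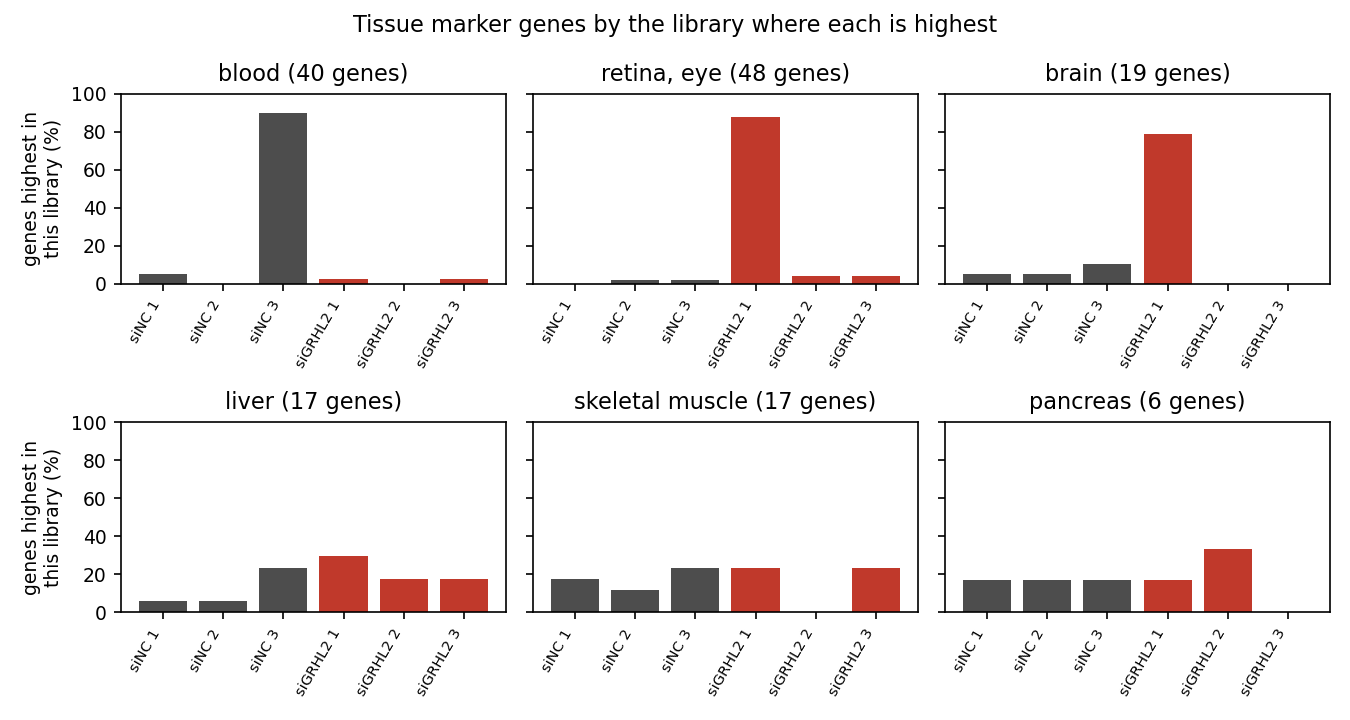
Share of marker genes (percent, y axis) that are highest in each of the 6 libraries (x axis), for 6 lists of tissue markers; bars are grey for siNC and red for siGRHL2. Blood markers peak in siNC replicate 3 (90.0%), retina and eye (87.5%) and brain markers (78.9%) in siGRHL2 replicate 1, and the liver, muscle and pancreas lists exceed 33.3% in no library.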

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

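No result changed direction past the threshold under any alternative run. GRHL2 lay between -0.83 and -0.79 in all fits, past the threshold in each. The counts of higher and lower genes stayed within 1.5 times their values under every filter, pseudocount, scaling and variance setting, but not when any 1 siGRHL2 library was left out. Over the 6 fits without 1 library, 1252 to 2584 genes were higher and 1273 to 2786 lower. Both highest counts came without siNC replicate 3, where blood markers were high, and both exceed those with 6 libraries. The count at 2-fold was 0 higher and 0 lower in every fit. With an estimated correlation, androgen response was at a camera adjusted p of 0.378 and epithelial junctions at 0.337. Without genes with sequence word matches (7 bases or more) they were at 0.263 and 0.194. The other fits gave 6.92e-05 to 0.0121 and 0.000107 to 0.0121 in the same order. The 0.000107 came from fry, which does not compare a list with the other genes. In the camera fits without 1 library, epithelial junctions were at 0.00195 to 0.00775. Without genes with word matches, fatty acid synthesis was at 0.242 and oxidative phosphorylation gained a call at 0.0395. The words were chosen because genes with them were lower, so this removal tends to take out lower genes by construction. It also leaves fewer genes to test, as 52 of 104 for androgen response. The other called lists stayed called after it, such as cholesterol synthesis at a camera adjusted p of 0.000953. The mesenchymal list ranged from 0.0302 to 0.597 over the fits without 1 library. The 0.597 came without siGRHL2 replicate 1, where 34 of its 59 genes in the file were highest. Its median was 0.005 without that library and siNC replicate 3, so its passes rested on siGRHL2 replicate 1. Whether RNA of other tissues raised these genes there was not tested. Among named genes, 77 of the planned comparisons and 30 of the added ones lost a call, and 1 of each gained one. The replicate number as a block gave 2198 higher and 2153 lower genes. It was not read as pairing the samples: libraries with the same number had deviations correlated at -0.05, 0.09 and -0.01, and 1 of the 6 libraries correlated best with its own number. What depth limits cannot be told from rlog values.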

Other observations

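Every test of an explanation in this part was settled after the values it measures had been seen, so the results describe these data and are not independent checks. The tissue markers were picked before their values were looked at.

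Groups of genes that share the letters at the start of their symbol were compared after the data were seen, over 174 groups of at least 10 genes, by an exact hypergeometric test that treats genes as independent. Of the 44 histone genes (HIST), 22 were higher. The fixed list holds 16 of the 44, and of the 28 outside it 13 were higher and 0 lower (exact hypergeometric p = 6.54e-05, not adjusted). Without siNC replicate 3 and siGRHL2 replicate 1, 8 of the 28 were higher. Of the FKBP group, immunophilins that help proteins fold, 8 of 15 were higher and 4 lower (adjusted p = 0.019 for the higher ones). Without those 2 libraries, 7 were higher and 1 lower. FKBP2 was at 0.50 and FKBP10 at 0.48, residents of the endoplasmic reticulum. FKBP5, the androgen-induced member, was at -0.42 and FKBP3 at -0.28. Solute carriers (SLC) had 63 of 261 higher and 28 lower (adjusted p = 0.00192). The transmembrane protein symbols (TMEM) had 49 of 180 higher and 24 lower (adjusted p = 0.000878), but 31 and 25 without those 2 libraries. The ribosomal groups RPL (adjusted p = 0.00192) and RPS (0.0414), which share genes with the fixed list, and the mixed group of symbols in ST (0.0447) also passed on the higher side. No group passed on the lower side, where RNF (0.0526), KIAA (0.0666) and KDM (0.0847) came nearest.

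In 2 libraries there were genes above a value shared by the other 5, 81 in siNC replicate 3 and 64 in siGRHL2 replicate 1, against 0 in each of the other 4. Of the blood cell markers, 90.0% were highest in siNC replicate 3, and of the retina and eye markers 87.5% were highest in siGRHL2 replicate 1; the most abundant such genes outside the marker lists include S100A9, at 11.08 in the first library against 10.75, and GFAP, at 10.93 in the second against 10.56. Of 40 liver, muscle and pancreas genes, 22.5% were highest in siNC replicate 3, which argues against a library that merely detects more low genes. A response to the GRHL2 siRNA is also argued against, since in 14.6% of the retina and eye markers both other siGRHL2 libraries lay above all siNC libraries. Traces of RNA from other samples handled alongside may be the source, a hypothesis that the labels cannot test.

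Fold changes rose with transcript GC content across genes (Spearman rho 0.314 over 12729 genes), with a median of -0.11 in the fifth of genes lowest in GC and 0.12 in the highest. GC content and length as the whole cause of the list calls is argued against, since 8 of 8 lists were still called after the correction, although the median of the ribosomal list fell from 0.14 to 0.09. Of 3966 called genes with a GC value, 3107 (78.3%) were called in the same direction after it. A library effect apart from the siRNA cannot be told apart from a group effect. The GC correlation spanned 0.581 over the siNC libraries, more than the 0.484 between the group means, but without the 2 libraries that hold other markers it spanned 0.073, against 0.664 between the groups. A biological origin was not tested.

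Genes with certain words of 8 bases in their 3' untranslated region were lower after siGRHL2, most of all TTACAACA (mean difference -0.09, 282 genes, z = -6.40). This and 4 other words lay below the lowest of 100 shuffles (-4.85), a pattern siRNA seeds matching other transcripts may leave. ATTACAAA went with higher values (z = 6.55), so genes with it were lower with siNC. Whether a seed of the control siRNA left this was not tested, and the removal of genes with word matches did not use this word. The other words of the same bases as TTACAACA had a mean z of -0.106, and would need -1.56 or lower for its z to pass the shuffles. Trends with base composition were removed before the scoring, so this mean was partly set in advance. It shows only that words of these bases were not lower as a class after that removal, and does not decide on base composition as the cause. Apart from this, of the 5 words TTACAACA and TCTGAGAA occur in GRHL2 itself and ACCTGTCA does not. The remaining 2 overlap TTACAACA by 7 bases and were not looked up singly. Of all scanned words, 9.9% occur in GRHL2. TTACAACA lies at chromosome 8 from 101636902 to 101636909 (GRCh38, exon 12, coding) and TCTGAGAA from 101664457 to 101664464 (exon 15, coding). In the spliced GRHL2 transcript, the reverse complement of 7 bases of ACCTGTCA lies just before TTACAACA, across the junction of exons 11 and 12. The seeds of both strands of 1 siRNA of 19 bases placed there would pair with these words. At most 0.028% of sets of 3 scanned words have such a placement. It was noticed before it was tested, and the siRNA sequences were not used here. For the words as a whole, seed matches remain open: the 5 words form 3 motifs, of which 2 are in GRHL2, which chance gives in 2.77% of cases counting the leading word of each motif and in 7.91% counting any of its words, and genes with at least 2 sites of TTACAACA differed from genes with 1 by -0.0286 (SE 0.0182). Short matches are common: at least 7 bases of TTACAACA, TCTGAGAA or ACCTGTCA lie in 52 of 104 androgen response genes. They lie in KLK3, KLK2, FKBP5, CDH1 and CGN but not in CLDN4, OVOL1, GRHL1 or FN1. Among the largest decreases, they lie in SYT7, RGL2, PSD4, WWC3, CARD14 and PRKCH but not in SDC4, STAP2, PROM2 or TFAP2C. Whether seeds lowered any single gene was not tested.

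With 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. The real split gave 4437 genes by limma and the other splits at most 0, so 1 split of 10 gave as many. For lists called by camera the real split gave 8 and the highest other split 12, and 6 of the 10 splits gave as many as the real one. Every other split mixes libraries of both siRNAs, so part of the siGRHL2 difference stays between its sides and part adds to the spread within them. The other splits therefore cannot show what either count would be without an siRNA effect. Why some of them called more lists was not tested, and the count of called lists by itself says little about siGRHL2.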
